A study of Caenorhabditis elegans with 2 samples.

How the data were processed

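The data are peak lists from chromatin immunoprecipitation and sequencing of tagged PQM-1 in whole L3 larvae, from 2 biological replicates of 1 group, with library fragments of 150 to 350 bp, per the labels. The extraction protocol is not given in the sources used here. Both samples come from the same strain and count as separate biological replicates, per the labels. For ce11 and for ce10, the authors deposited a relaxed list for each replicate, a relaxed list called on both replicates together, and an optimal list kept at a threshold on the irreproducible discovery rate, which measures how far ranked replicate lists match. The labels name a possible control library, which was not used here, and signal tracks were not used here either. The aligner, the peak caller and the threshold are not given in the sources used here.

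The signal value of each peak is a score that the authors deposited in the narrowPeak format, with its scale not stated, and it was used only to rank, describe and filter peaks within a list. The q value is deposited by the authors as −log10, and every optimal peak sits at the highest value of that column, so q cannot rank that list. A further column gives the summit position within the peak, as deposited. The optimal list on ce11 was exactly the strongest 5560 of the 30000 peaks of the pooled list, those with a signal of 23.8 or more. The relaxed lists of the replicates held 26022 and 30000 peaks. Depth is unknown because peak lists give no reads. Intervals of shares are exact binomial (Clopper-Pearson) at 95%, the interval of the X to autosome ratio is computed from the exact interval of the share of peaks on X, and intervals of differences use the normal approximation, and all cover counting error only, and p-values over peaks or genes treat neighbouring peaks as independent.

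The ce11 lists were read against the WBcel235 genome, which is the same assembly, and the Ensembl 115 annotation. No coordinates were converted between builds, and the ce10 lists entered only comparisons that need no sequence or annotation. Peaks counted as shared with at least 1 bp of overlap, and the overlap code gave 3631 shared peaks, as did bedtools 2.31.1. Promoters ran from 1000 bp upstream to 250 bp downstream of the 5' end of each protein-coding gene. The promoter share was set against 1000 random placements of the peaks on their own chromosomes. Motifs were counted on both strands within 50 bp of the summit and in windows of the same size 500 bp away, with an exact sign test over summits and upstream flanks. Upstream flanks are those toward lower genome coordinates, whatever the strand of the nearest gene. Bound genes inside and outside each of 27 gene lists were compared by Fisher's exact test with Benjamini-Hochberg adjustment over the lists. Rank correlations used 100000 permutations. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

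The lists, tests, named genes and alternatives were chosen before the data were examined, except where the text says otherwise. The named genes are those nearest to the 20 strongest optimal peaks, leaving out peaks within 20 kb of pqm-1 and unc-119, up to 3 bound members with the strongest promoter peak per list, 12 genes named in any case, and the 10 heptamers with the largest excess at summits. Of the list symbols, hsp-16.11, sodh-1 and pes-2 were not found under that name in the annotation. It gives 2 genes the name hsp-16.1 and 2 the name hsp-16.48, and all 4 were kept. The alternatives were other overlap rules, list lengths, promoter and motif windows, flanks, backgrounds and gene models, the ce10 lists, and each replicate alone, which means as many of the other replicate's strongest peaks as the optimal list holds.

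The tests were also run on simulated data, after the first results had been seen. Of 100 simulated lists with 30% of members given a promoter summit, 100 were called, and 4 of 440 unchanged lists were called, over 19973 genes. The lists given summits held 83 to 270 genes, so the power for smaller lists was not tested. Members were drawn at random, so families of neighbouring genes were not simulated either. The motif test passed the threshold for 2 of 100 sets of 5560 random positions, and the placement test for 1 of 50 sets of 2000. A heptamer planted in 10% of windows ranked 1.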

Results

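Chromatin immunoprecipitation followed by sequencing was used to map where PQM-1, a zinc finger transcription factor of the nematode Caenorhabditis elegans, was bound in whole larvae at the L3 stage. The worms were of strain OP201, which carries an eGFP-tagged pqm-1 transgene in an unc-119 mutant background, and the sexes were pooled. The design held 1 group with 2 biological replicates, so the comparisons are between the replicates, between bound and unbound parts of the genome, and between strong and weak peaks. There was no second condition. The peak lists carry no read counts, so the depth of each library is unknown. Positions are on the ce11 build. Each list gives every peak a signal value set by the authors, a score whose scale is not stated, which was used here only to rank, describe and filter peaks within a list. A gene is called bound below when an optimal peak had its summit in the gene's promoter, from 1000 bp upstream to 250 bp downstream of the 5' end.

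The first question was how far both replicates marked the same places. The authors' optimal list held 5560 peaks with a median width of 340 bp, covering 1.72% of the genome. Of these, 5555 overlapped a peak of the relaxed list of replicate 1 and 5197 overlapped one of replicate 2. The strongest peak, upstream of Y37A1A.2 on chromosome IV, was also the strongest of each replicate list. When each replicate was reduced to its 5560 strongest peaks, 3631 of replicate 1's peaks (65.3%, exact 95% interval 64.04 to 66.56) overlapped one of replicate 2. Randomly placed peaks gave 3.73%. Among replicate 1's strongest 1000 peaks, 99.3% overlapped some peak of replicate 2, against 77.4% of those ranked 4001 to 5560.

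Across the 5192 optimal peaks seen in both replicates, the signal values had a Spearman rho of 0.516 (permutation p = 1e-05, the smallest the permutations can give). This correlation is across peaks, which are not independent replicates. With the q value column in place of the signal rho was -0.0267 (permutation p = 0.0558), and 74.6% of these peaks were at the highest q of both lists. The summits of the paired peaks lay a median of 37 bp apart. Sharing fell to 46.1% over the whole relaxed lists.

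**Figure D1:**
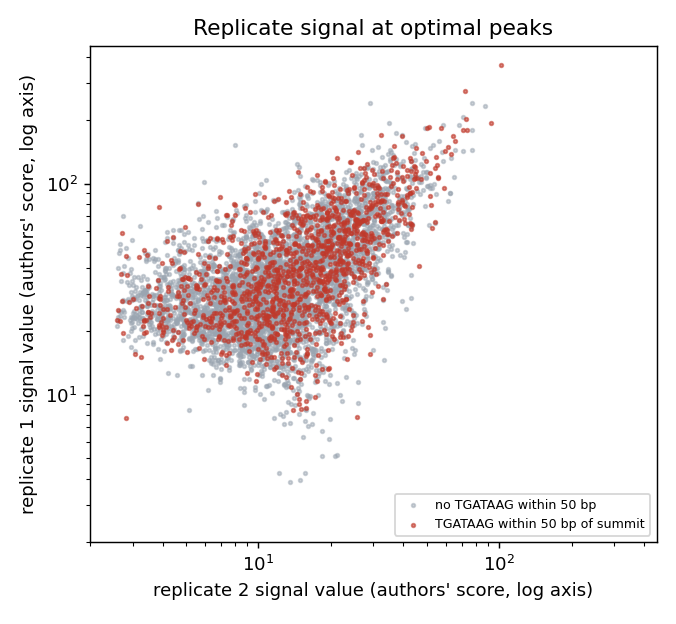
Signal value of replicate 1 (vertical, log axis) against replicate 2 (horizontal, log axis) at the 5192 optimal peaks found in both, each point a peak, red where TGATAAG lay within 50 bp of the pooled summit. The values rose together with a wide scatter (rho 0.516).

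The next question was where the peaks lay relative to genes. Promoters of protein-coding genes held 2753 of the 5560 summits (49.5%, exact 95% interval 48.2 to 50.8), against a mean of 22.2% for randomly placed peaks, a 2.23-fold excess (permutation p = 0.002, two-sided, the smallest the placements can give). Coding exons outside promoters held 2.59% of summits, although they make up 19.7% of the genome. Introns held 21.1% of summits and 30.0% of the genome, and intergenic sequence held 24.4% of summits and 25.03% of the genome. Of all summits, 66.3% lay upstream of the nearest 5' end, and 26.8% lay more than 2000 bp from any 5' end. The promoter share without replicate 1 was 43.8% and without replicate 2 was 50.1%.

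The strongest peaks lay near genes of several kinds. The top peak (chromosome IV, 13919244 to 13919554) had a signal of 471.6 and lay in intergenic sequence, at -6377 bp from the 5' end of Y37A1A.2. The peak ranked 2 (IV, 3899870 to 3900165, signal 345.7) was at the promoter of srz-62, a chemoreceptor gene. The peak ranked 6 (X, 3256857 to 3257108, signal 278.2) was at the promoter of lbp-3, which encodes a lipid-binding protein. Intergenic peaks upstream of laat-1, a lysosomal amino acid transporter gene, and xdh-1, a xanthine dehydrogenase gene, ranked 5 and 16. The promoter peak of cpr-4, a cathepsin B family protease gene, ranked 17, and an intergenic peak upstream of nhr-31, a nuclear hormone receptor gene, ranked 20. The other genes nearest to the 20 strongest peaks were frm-10, irld-18, T24E12.13, R12C12.9, abhd-3.2, T23E1.1, asp-13, F49E12.12, srlf-7, C08E8.3, B0507.3, sdz-19 and zig-13.

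Of 12 genes named beforehand, 10 were unbound at their promoters. Among the 12, elt-2, the GATA factor that directs intestinal gene expression, was bound (X, 10480675 to 10480886, signal 128.0, rank 216), and so was mtl-1, a metallothionein gene (V, 6692143 to 6692253, signal 83.2, rank 845). The promoters of pqm-1, unc-119, daf-16, hsf-1, skn-1, sod-3, hsp-16.2, vit-2, fat-7 and dod-24 held no optimal summit. Those of daf-16 and skn-1 each held a peak of the pooled relaxed list, and the others held none. The daf-16 peak had a signal of 20.997, not far under the 23.8 at which the optimal list ends, and the skn-1 peak was weaker. The gene bodies of daf-16 and skn-1, whose products are transcription factors of the insulin and oxidative stress pathways, held 4 and 6 optimal summits. With the 5' ends of all transcripts counted, an alternative chosen after seeing the data, skn-1 was bound and daf-16 was not. With the wider promoter hsf-1, a heat shock factor gene, was bound, its nearest optimal summit at -1988 bp. Near fat-7, a stearoyl-CoA desaturase gene, the nearest optimal summit was 2383 bp downstream of the 5' end and outside the gene.

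The sequence at the summits was then compared with flanks 500 bp away, where upstream means toward lower genome coordinates and not relative to a gene. The heptamer TGATAAG, known as the DAF-16-associated element and linked with PQM-1 in earlier work, was within 50 bp of 1327 summits (23.9%, exact 95% interval 22.75 to 25.01), against 2.27% of upstream flanks, a 10.5-fold excess (exact sign test, two-sided, adjusted exact p = 4.5e-268 over 5 motifs). The DAF-16 site GTAAACA was at 3.11% of summits and 1.37% of flanks (exact sign test, adjusted exact p = 5.16e-10). AGATAA, a form of the GATA site, was at 11.9% and 6.21% (exact sign test, adjusted exact p = 2.76e-25). TGATAAG also holds GATA, and sites of that form are not in the AGATAA count. The E-box CACGTG was at 4.98% and 1.67% (adjusted exact p = 1.24e-22), and GAGAGAG at 8.29% and 1.38% (adjusted exact p = 7.37e-69), both by the same exact test. Within the strongest 1000 peaks the GTAAACA difference did not pass the threshold, at 2.60% (exact sign test, p = 0.371).

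With no prior choice, TGATAAG, counted under its other strand CTTATCA, ranked 1 of 8192 heptamers by excess at summits, at 21.7 percentage points. The heptamers ranked 2 to 9, GATAAGA, CTGATAA, ACTGATA, GTTATCA, TTATCAA, ATAAGAA, GTGATAA and AACTGAT, each hold TGAT or ATAAG on 1 strand. AGAGAAA, ranked 10, had an excess of 7.60 percentage points. The 209 shuffled heptamers of TGATAAG averaged 1.48% at summits and 1.60% in flanks. The highest among them was GTGATAA, ranked 8 above, with an excess of 8.06 percentage points. The A-rich AAAAATT stood last, at 9.69% of summits and 24.2% of flanks. Summits and flanks thus differed in base composition. Shuffled forms of AGATAA, GTAAACA, CACGTG and GAGAGAG were not counted, so how far composition enters their excess was not tested.

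**Figure D2:**
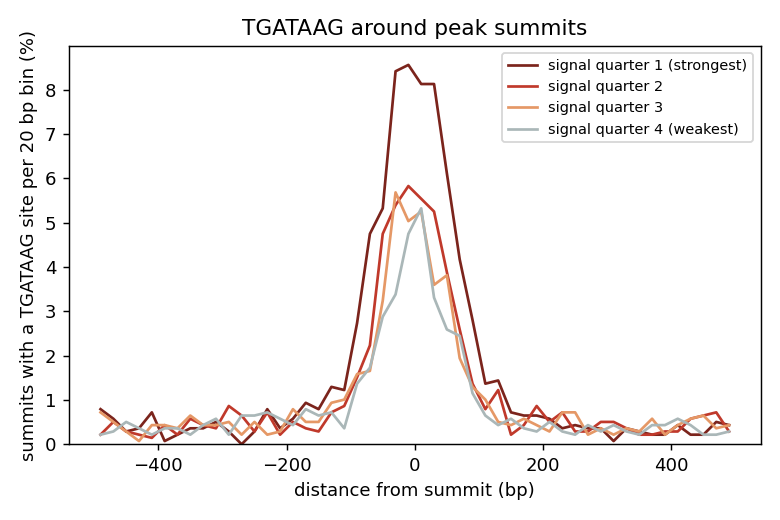
Percent of summits with a TGATAAG site per 20 bp bin (vertical) by distance from the summit in bp (horizontal), a line for each block of 1390 peaks by signal rank. The highest bin reached 8.56% in the strongest block and 5.32% in the weakest, both beside the summit.

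Strong and weak peaks were compared to see whether sequence and place changed with signal. TGATAAG was at 33.4% of the strongest 1390 optimal peaks and at 17.6% of the weakest 1390 (Fisher's exact test, two-sided, p = 8.48e-22). Promoters held 48.7% of the strongest 1390 and 48.8% of the weakest 1390 (Fisher's exact test, p = 1). Without replicate 1, on replicate 2's strongest peaks, the promoter difference was 9.78 percentage points in favour of the strongest 1390 (Fisher's exact test, p = 2.22e-07), a setting added after seeing the data.

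**Figure D3:**
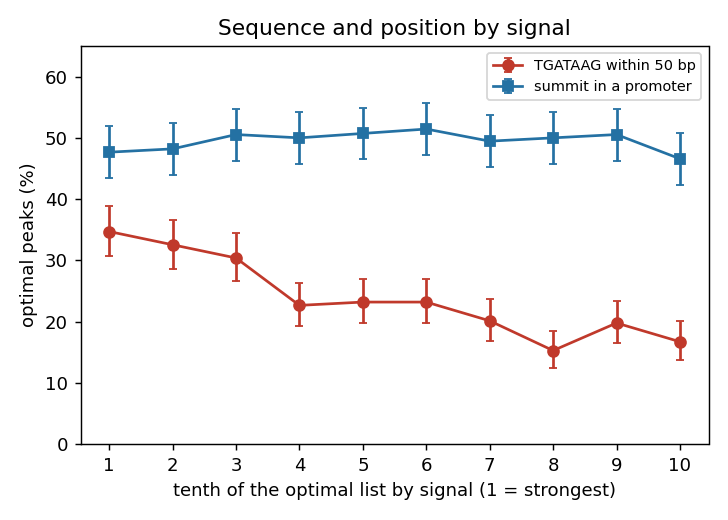
Percent of optimal peaks (vertical) with TGATAAG within 50 bp of the summit (red circles) or with the summit in a promoter (blue squares), by block of 556 peaks in the signal ranking (horizontal), with exact 95% intervals. The TGATAAG share fell from 34.7% to 16.7% between the strongest and the weakest block, and the promoter share stayed between 46.6% and 51.4%.

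Of 19973 protein-coding genes, 3260 (16.3%) were bound. Ribosomal, intestinal and metabolic gene groups held more bound promoters than the rest of the genome, and chemoreceptor, neuropeptide, collagen and hedgehog-related genes held fewer. Of 27 gene lists, 12 had more bound promoters and 4 had fewer at adjusted p under 0.05 (Fisher's exact test, two-sided, Benjamini-Hochberg).

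Cytosolic ribosomal protein genes were bound in 61 of 78 cases (78.2%, odds ratio 18.7, adjusted exact p = 2.7e-32), and in 49 of 78 without replicate 1 (odds ratio 10.7). None of their 58 promoter peaks held TGATAAG within 50 bp, as given below. The control library was not analysed here, so signal at these promoters that does not depend on PQM-1 was not tested for. The promoter peaks of rpl-20 (signal 223.1, rank 21), rpl-3 (176.6, rank 52) and rpl-35 (160.7, rank 81) were the strongest among them. Of the genes for the vacuolar proton pump, 11 of 20 were bound (adjusted exact p = 0.000256), led by vha-1, vha-12 and vha-8. Of the mitochondrial respiratory chain genes, 17 of 38 were bound (adjusted exact p = 0.00012), led by cox-5A, cox-5B and atp-3. Within the strongest 1000 peaks neither of these last lists passed. The proton pump had 2 of 20 bound (odds ratio 3.76 against 6.28, adjusted exact p = 0.232) and the respiratory chain 4 of 38 (3.99 against 4.17, adjusted exact p = 0.0625).

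Intestine markers were bound in 15 of 20 cases (75.0%, odds ratio 15.4, adjusted exact p = 6.93e-08), and in 13 of 20 without replicate 2 (odds ratio 9.39). Among them were act-5, an actin of intestinal microvilli (signal 152.6), elt-2 (128.0) and asp-1, an aspartyl protease gene (121.5). Of the markers of other tissues, 1 of 18 was bound for hypodermis (wrt-10), 2 of 16 for body wall muscle (unc-60 and deb-1), 2 of 13 for pharynx (pha-4 and pgp-2), 2 of 22 for neurons (egl-21 and snb-1) and 1 of 20 for germline (cgh-1). None of these lists passed (adjusted exact p from 0.314 to 1). The markers were set beforehand, and how specific each is to its tissue, such as pha-4 and pgp-2 to the pharynx, was not checked. The small counts moved with the replicate left out, to 1 of 13 for pharynx without replicate 2 (odds ratio 0.42 against 0.932), and without replicate 1 to 3 of 22 for neurons (0.987 against 0.512) and 0 of 18 for hypodermis (exact 95% upper limit 18.5%).

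Endoplasmic reticulum stress, transferase, cytochrome P450 and hypoxia lists also passed. Of the endoplasmic reticulum chaperone and unfolded protein response genes, 11 of 18 were bound (adjusted exact p = 8.59e-05), including xbp-1, a transcription factor of that response (signal 139.6, rank 151), hsp-3, an Hsp70 chaperone (94.7), and pdi-3, a disulfide isomerase (79.7). The glutathione and glucuronosyl transferases had 48 of 114 bound (adjusted exact p = 4.99e-10), led by gst-42, ugt-20 and gst-22. The cytochrome P450 genes had 23 of 74 bound (adjusted exact p = 0.00317), led by cyp-37B1, cyp-13A8 and cyp-25A2. A further setting kept only the first gene along the chromosome of each run of neighbours within 5 kb and dropped the others, bound or not. The P450 genes were then at 12 of 48 (odds ratio 1.72 against 2.32, adjusted exact p = 0.173). Within the strongest 1000 peaks 4 of 74 were bound (odds ratio 1.93, adjusted exact p = 0.311). The hypoxia and hydrogen sulfide list had 5 of 9 bound (Fisher's exact test, adjusted exact p = 0.0157), including sqrd-1, rhy-1 and nhr-57, and 0 of 9 within the strongest 1000 peaks (exact 95% upper limit 33.6%).

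Of the lipid genes, 13 of 41 in fatty acid synthesis and desaturation (adjusted exact p = 0.0288) and 12 of 35 lipases and lipid-binding proteins (adjusted exact p = 0.0167) were bound. They included acs-7 and acs-2, acyl-CoA synthetase genes (signals 178.3 and 115.9), elo-2, a fatty acid elongase gene (118.5), lbp-3, lbp-7 and lipl-5. The fatty acid list counts all 22 acs genes along with 19 genes named singly. Of the acs genes 6 were bound, which did not pass alone (odds ratio 1.92, Fisher's exact test, adjusted exact p = 0.321 over 175 prefixes). The 19 genes were not tested without them. The lips genes of the lipase list had 0 of 14 bound (exact 95% upper limit 23.2%). The narrower promoter left the fatty acid list at 8 of 41 (odds ratio 1.70 against 2.39, adjusted exact p = 0.211), while the wider promoter gave 24 of 41 (5.26, adjusted exact p = 9.9e-07) and the lists without replicate 1 gave 16 of 41 (4.02, adjusted exact p = 0.000186). The lipase list did not pass in the strongest 2780 peaks (6 of 35, odds ratio 2.33 against 2.68, adjusted exact p = 0.0936) or the strongest 1000 (3 of 35, 3.17, adjusted exact p = 0.177). Among innate immunity effectors 72 of 312 were bound (adjusted exact p = 0.004), with the strongest promoter peaks at clec-265, clec-78 and spp-14. By name prefix, a grouping chosen after seeing the data, the clec genes did not pass, at 49 of 240 (Fisher's exact test, adjusted exact p = 0.226 over 175 prefixes). The lys genes passed, at 7 of 10. With only the first gene of each run of neighbours within 5 kb kept, the list was at 43 of 204 (odds ratio 1.38 against 1.55, adjusted exact p = 0.11). Of the nuclear hormone receptors, 68 of 270 were bound (adjusted exact p = 0.000469), led by nhr-68, nhr-291 and nhr-8. When only genes with a relaxed peak at the promoter served as background, 6 of the 12 lists did not pass: both lipid lists, the P450 genes, the nuclear hormone receptors, the respiratory chain and the hypoxia list (odds ratios from 1.39 to 2.94, adjusted exact p from 0.0555 to 0.461). These lists also held fewer genes there. The lipase list was at 2.36 against 2.68 on 21 genes, and the hypoxia list at 2.94 against 6.42 on 8 genes. With this background the odds ratio was 9.12 for the ribosomal protein genes, 6.64 for the intestine markers and 0.217 for the chemoreceptor genes, all still called.

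Chemoreceptor genes were bound in 31 of 1309 cases (2.37%, odds ratio 0.116, adjusted exact p = 1.6e-62), led by srz-62, srr-6 and sri-39. Neuropeptide and insulin genes were bound in 4 of 140 cases (adjusted exact p = 4.13e-06), among them ins-12, ins-39 and ins-7. The ins-7 peak overlapped no peak of replicate 2. By name prefix, a grouping chosen after seeing the data, the neuropeptide genes had 0 of 71 (nlp) and 0 of 31 (flp) bound (exact 95% upper limits 5.06% and 11.2%). The insulin genes (ins) had 4 of 38 bound and did not pass alone (odds ratio 0.603, Fisher's exact test, adjusted exact p = 0.673 over 175 prefixes). Collagen genes were bound in 8 of 175 cases (adjusted exact p = 1.16e-05), led by col-63, col-151 and col-74. Hedgehog-related genes were bound in 3 of 83 cases (adjusted exact p = 0.00125), namely ptr-21, wrt-3 and wrt-10, the last with no overlapping peak in replicate 2. With only promoters that had a relaxed peak as background the adjusted exact p was 0.167. Within the strongest 1000 peaks the neuropeptide and insulin list (1 of 140) and the hedgehog-related list (0 of 83, exact 95% upper limit 4.35%) did not pass, each with adjusted exact p = 0.311.

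The calls of the lists tied to insulin signalling depended on the setting, and none passed in the setting used throughout. DAF-16-induced stress and longevity genes had 9 of 28 bound (odds ratio 2.43, adjusted exact p = 0.0542), including lys-8, a lysozyme gene (signal 136.0), mtl-1 and dod-6. Genes lower in daf-2 mutants had 6 of 16 bound (odds ratio 3.08, adjusted exact p = 0.0542), including dod-19, aqp-1 and dod-22. With only the first gene of each run of family members within 5 kb kept, both passed, at 9 of 21 and 6 of 15 (adjusted exact p = 0.00898 and 0.0447). The DAF-16 list passed under 5 of 10 alternatives, the others being the narrower promoter (adjusted exact p = 0.0306), only promoters with a relaxed peak as background (odds ratio 5.31, adjusted exact p = 0.0317), the lists without replicate 1 (adjusted exact p = 0.0201) and the 5' ends of all transcripts, chosen after seeing the data (adjusted exact p = 0.0351). Without replicate 2 it had 8 of 28 bound (odds ratio 2.02, adjusted exact p = 0.18), and without replicate 1 the genes lower in daf-2 mutants had 4 of 16 bound (2.08, adjusted exact p = 0.337). The 6 bound by the optimal list include ins-7, whose peak overlapped none of replicate 2. The insulin, TOR and stress signalling genes had 5 of 19 bound (adjusted exact p = 0.314), led by the kinase genes akt-1, sgk-1 and akt-2, and 9 of 19 with the wider promoter (odds ratio 3.34 against 1.83, adjusted exact p = 0.018). GATA factors had 3 of 11 bound (elt-2, elt-4 and elt-7, odds ratio 1.92, adjusted exact p = 0.495) and 2 of 11 without replicate 2 (odds ratio 1.12), where elt-7, which had no peak in replicate 1, was unbound, histones 11 of 72 (his-37, his-61 and his-62 the strongest, adjusted exact p = 1), and vitellogenins, the yolk protein genes, 0 of 6, which allows a share of up to 45.9% by the exact 95% interval (Fisher's exact test, adjusted exact p = 0.673). Near-identical copies among the histone and small heat shock genes are uncertain, since reads could be shared between copies.

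**Figure D4:**
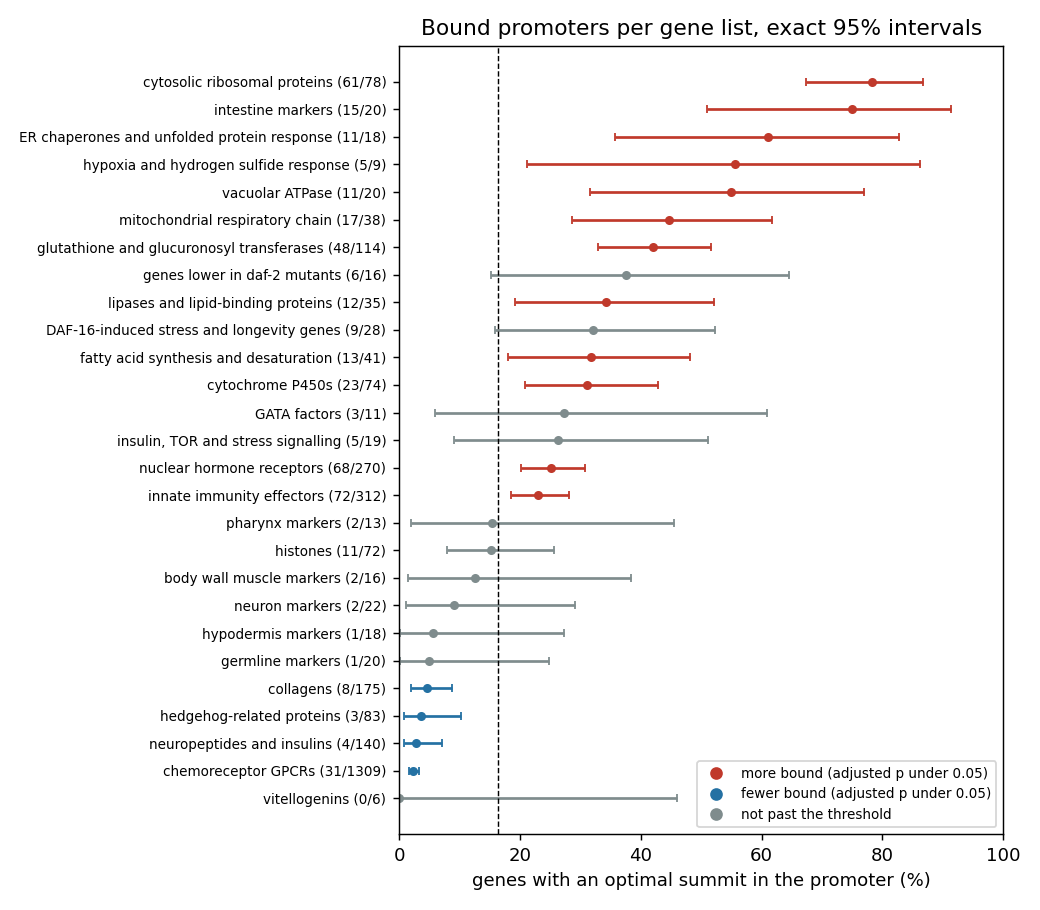
Percent of genes with an optimal summit in the promoter (horizontal) for the 27 gene lists (vertical, bound genes of all genes in brackets), with exact 95% intervals, red for more and blue for fewer bound than the rest of the genome at adjusted p under 0.05. The dashed line marks the 16.3% of all protein-coding genes, and the lists range from 0 of 6 vitellogenins to 61 of 78 ribosomal protein genes.

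The X chromosome held 67.2 optimal peaks per Mb and the autosomes 52.9, a ratio of 1.27 (95% interval 1.19 to 1.35). Chromosome I had the fewest, at 47.8 per Mb. Of 2731 genes on X, 17.2% were bound, against 16.18% of 17242 on the autosomes (Fisher's exact test, two-sided, p = 0.164). The gene difference passed in the strongest 2780 peaks (Fisher's exact test, p = 0.0014), within the strongest 1000 peaks (p = 0.0485) and without replicate 1 (p = 0.00255).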

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

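The test in this part was chosen after seeing the shares below, with its prediction written before it was run on the first rank range, and it was extended to the other ranges later. The sequence at pooled peaks under the authors' threshold is described in no comparison of the report, and these peaks were singled out because TGATAAG was more frequent at their summits than in their flanks. The share was 11.2% at pooled peaks ranked 5561 to 10000 (flank 2.34%, exact sign test p = 7.44e-64), 3.63% at those ranked 10001 to 20000 (flank 1.52%, p = 1.09e-21) and 2.05% at those ranked 20001 to 30000 (flank 1.66%, p = 0.0472).

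Spill-over from stronger neighbours is a candidate explanation. Without summits within 1000 bp of an optimal summit the share was 11.2% (11.25% with a further digit, flank 2.13%) for ranks 5561 to 10000 and 3.45% (flank 1.36%) for ranks 10001 to 20000, which argues against spill-over as the whole cause there. For ranks 20001 to 30000 the share was 1.96% (flank 1.35%), a 1.45-fold excess, which the bound written beforehand would count for spill-over. The excess was 1.23-fold with the neighbours in, so leaving them out did not lower it and the test decides nothing there, a reading chosen after its result was seen. No biological explanation was tested.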

How the results depend on the processing

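The alternatives that used the 5' ends of all transcripts, the sharing counted from replicate 2 and the signal trend in each replicate were chosen after seeing the data. The promoter share and the TGATAAG excess kept their direction and passed their tests under all 8 and 9 alternatives, and the rise of TGATAAG with signal under all 4. Of the 8, leaving out peaks near pqm-1 and unc-119 removed 0 peaks and tests nothing. Sharing of 65.3% became 61.0% with the summit inside the other peak, 53.1% with reciprocal overlap of 50%, 60.7% for the strongest 1000 peaks and 46.1% for the whole lists. The rank correlation changed sign to -0.0267 by q value, where 74.6% of the peaks sit at the ceiling of both lists. Lists with more bound promoters numbered 12, and 7 with only genes that had a relaxed peak as background or with the strongest 1000 peaks, where those with fewer fell from 4 to 2. The X to autosome ratio was 1.29 in the strongest 2780 peaks and 1.25 in the strongest 1000 peaks, and ranged from 1.26 to 1.30 without 1 replicate at a time, with the gene test passed in all of these but the setting without replicate 2. The promoter trend ranged from -2.66 to 9.78 percentage points without 1 replicate at a time. The hypoxia list had an odds ratio of 0 in the strongest 1000 peaks, where fewer peaks leave 0 of 9 bound. Over the 27 lists and 10 alternatives, 245 calls were unchanged, 17 were lost with the direction kept, 7 were gained, and the hypoxia call above was lost with an odds ratio under 1. Of the 69 bound genes named from the lists or in any case, 63 were bound without replicate 1 and 67 without replicate 2. Most of these were named for having the strongest promoter peaks of their list. Of all 3260 bound genes, 2263 stayed bound without replicate 1 and 2996 without replicate 2. For the changes with no cause named here, the cause was not tested. Depth is unknown, so it cannot be said which peaks of 1 replicate lie under the detection limit of the other.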

Other observations

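The bases beside the element, the 2 motifs and the lists compared by motif, and the groups named below were chosen after seeing the data, while the predictions for the explanations weighed below were written before their tests were run. The bases beside TGATAAG went with how often a site was occupied, meaning within 50 bp of an optimal summit. Of 18686 sites in the genome, 8.46% were occupied. The share was 14.01% for CTGATAAG, 6.03% for ATGATAAG and 6.46% for TTGATAAG, and 12.0% for TGATAAGA against 2.57% for TGATAAGT. With both sides together it was 18.7% for CTGATAAGA (exact 95% interval 16.9 to 20.6) and 1.96% for ATGATAAGT (1.17 to 3.08). Sites in promoters were occupied in 13.6% of cases and sites in coding exons in 1.36%.

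The groups of bound genes differed in whether their promoter peaks held the element. None of the 58 promoter peaks of bound ribosomal protein genes had TGATAAG within 50 bp (exact 95% upper limit 6.16%), against 22.3% of the other promoter peaks (Fisher's exact test, adjusted exact p = 3.37e-05 over 36 list and motif pairs). It was at 31 of 69 peaks of innate immunity effectors (44.9%, adjusted exact p = 0.000341) and at 14 of 31 of chemoreceptor genes (45.2%, adjusted exact p = 0.0413). Among intestine markers it was at 8 of 15 (53.3%, Fisher's exact test, adjusted exact p = 0.0516). It was at 0 of 17 respiratory chain peaks (exact 95% upper limit 19.5%) and 0 of 11 endoplasmic reticulum peaks (28.5%), which did not pass (adjusted exact p = 0.198 and 0.445). GAGAGAG, the other motif, was at 0 of 69 immunity effector peaks (exact 95% upper limit 5.21%), against 8.12% of the other promoter peaks (Fisher's exact test, adjusted exact p = 0.0494).

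Grouping genes by name prefix gave 175 groups of at least 10 genes, of which 14 were bound more often and 23 less often at adjusted p under 0.05. Among these, the lysozyme genes (lys) were bound in 7 of 10 cases, the galectins (lec) in 7 of 12, the proteasome regulatory subunits (rpn) in 7 of 13 and the F-box genes named fbxa in 45 of 170. The F-box genes named fbxb went the other way, with 3.85% bound (odds ratio 0.204, adjusted exact p = 0.00196). The major sperm protein genes (msp) were bound in 0 of 31 (exact 95% upper limit 11.2%). Promoters of 30.7% of 612 tRNA genes and 32.9% of 346 snoRNA genes held a summit, against 3.69% of 15363 piRNA genes. In all these groups each gene was counted on its own, including neighbours that share a peak. The gap upstream of mxl-3, a gene for a transcription factor of the bHLH class, held 9 optimal summits in 10397 bp.

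Some peaks were in the strongest 5560 of only 1 replicate, 1929 for replicate 1 and 1891 for replicate 2. Chance enrichment in a single library would leave TGATAAG near its flank level, and the ratio was 7.53 for replicate 1 and 3.31 for replicate 2, which argues against chance for these sets as a whole. A lower rank in the other library is a candidate explanation for most of them, since 67.3% and 62.0% overlapped the other replicate's full list, against 19.1% and 16.19% for random placement. The rest remain open, chance included, since TGATAAG was not counted for them on their own. No biological explanation was tested.

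The rise of TGATAAG with signal could come from base composition or from promoter position. The unadjusted difference between the strongest and weakest 1390 peaks was 15.8 percentage points. Averaged over 5 strata of GC content it was 14.6 (95% interval 11.5 to 17.6), with single strata from 5.52 to 20.2. This argues against base composition as the whole cause. Promoters held 48.7% of the strongest and 48.8% of the weakest 1390 peaks, which argues against a difference in promoter share as the cause. Outside promoters the TGATAAG difference was 13.01 (8.45 to 17.6). With promoter shares so alike, that test could hardly have come out otherwise and adds nothing on position. No biological explanation was tested.

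Around the tagged gene, the pooled relaxed list held 2 peaks within 20 kb of pqm-1, at percentile 1.79 of all protein-coding genes, so no excess of peaks was seen there. The control library was not analysed here and whether it carries the same copies is unknown, so this count leaves the effect of the copies open, a reading chosen after its result was seen.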
